A study of Mus musculus with 15 samples.

How the data were processed

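Whole-lung RNA of 15 mice was measured on Illumina mouse beadchips, 1 array per mouse. The mice were grouped by the genotype and challenge that the labels give: 4 unchallenged wild types, 3 unchallenged homozygous mutants, 4 challenged wild types and 4 challenged homozygous mutants. Each array has its own mouse, so replicates are separate animals. Per the labels' protocols, RNA was extracted with Trizol, cleaned on columns, checked on gels, and amplified to biotin-labelled cRNA. The submitters' processing notes name GenomeStudio 2011.1 without stating its role.

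The deposited table of raw signals gives, per the file headers, a linear intensity and a detection p-value for each of 25697 probes on each array. The detection p-value deposited by the authors moves in steps of 0.00125. The authors' series matrix holds a further set of linear intensities, of which 21.1% to 21.2% per array lie below 0. How the authors normalized that set is not given in the sources used here, and it served only as an alternative. Of the probes 23978 have 1 gene symbol in the platform annotation, 0 have several and 1719 have none. The Entrez ids of 23962 probes were found in a RefSeq gene table of assembly GRCm38.p6, and 0 probes were renamed.

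Raw intensities were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, with negative control behaviour inferred from the detection p-values and an offset of 16, and taken to log2. A probe was tested if its detection p was under 0.05 on at least 3 arrays, which left 14396 probes, 13535 of them naming 10194 genes. A linear model with a mean for each of the 4 groups was fitted to all 15 arrays with lmFit and eBayes (11 residual degrees of freedom), since the groups then share an estimate of the spread. The contrasts were challenge in wild types, challenge in mutants, genotype without challenge, genotype with challenge, and the interaction. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all probes tested, with a threshold of 0.05. A gene is given by its brightest probe unless a probe is named. Where a probe was not detected on any array of a group, a fold is a lower bound: the brighter group's mean over the dimmer group's mean of, per array, the higher of the lowest signal among detected probes and the probe's own. Mean signal and detection per array were compared with exact permutation tests. The number of arrays limits the precision.

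Gene lists for cell types and processes of the lung, 36 in all, were fixed together with the design, the tests, the rule for named genes and most alternatives before the data were examined. A list entry was matched to an older name of a gene only where it is no other gene's current symbol. The 33 lists with at least 4 tested genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The genes named are Ifit2 and the sex-linked genes of the label check, the 8 highest and 8 lowest changes per contrast among genes past the threshold whose groups do not overlap, and the 4 members with the smallest p of each list that passed or held at least 2 called genes. Interferon-stimulated genes, genes of the response to TNF or lipopolysaccharide, and neighbours of Ifit2 on chromosome 19 were always included. For the interaction the 5 genes with the smallest p are named. From these a smaller set is given in the text. Lists of exocrine pancreas, pancreatic islet and salivary gland genes were added after the data had been seen.

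On simulated arrays, with 200 of 14396 probes changed, the model recovered 74.6% of 2-fold changes for challenge in wild types and 64.2% for challenge in mutants. It recovered 64.2% for genotype without challenge, 70.1% for genotype with challenge and 28.4% for the interaction. Noise was drawn independently for each probe there, so variation shared across genes was absent. With 88 to 139 calls the adjusted threshold was also easier to pass than where few probes change. Recovery may therefore be overstated. On simulated arrays with no difference, over 20 draws on 10194 genes, camera with the preset correlation called a median of 5.5, 7.5, 6, 5 and 8 lists in those contrasts, whereas with an estimated correlation it called at most 1, 0, 0, 1 and 2 and fry at most 1, 3, 1, 1 and 2. Calls at the preset correlation are therefore given with the p at an estimated correlation beside them.

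Alternatives were no background correction, normexp with an offset of 50, median scaling, cyclic loess, the authors' series matrix values, no filter, a stricter filter, eBayes with trend and robust fitting, array weights, a minimum of 1.5-fold, a fit to only the groups compared, the replicate number as a block, and leaving out each array in turn. Fits without doubted arrays, and with mean signal or the level of skeletal muscle, squamous or exocrine pancreas genes as a covariate, were chosen after seeing the data.

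Several tests of explanations were revised after a first outcome had been seen. A first test of pancreatic RNA, which asked for at least 80% of exocrine genes to be higher on every challenged array, found 6 of 27, and the detection of islet hormones took its place. A test of mixing that the 2 arrays in question passed was left open, because an absence of mixing passed on 1 of them as well. A test of a genotype effect shared by the unchallenged mutants, which rested on 1 array, was left open. A count of adjusted calls near Ifit2 was replaced by a count at an unadjusted p under 0.05.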

Results

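Gene expression was measured in whole lung of 15 C57BL/6 mice aged 22 weeks, with 1 Illumina beadchip array per mouse. The mice differed in genotype and in exposure to ovalbumin (OVA), an egg-white protein used to provoke allergic airway inflammation. The groups were unchallenged wild types (n = 4), unchallenged homozygous mutants (n = 3), challenged wild types (n = 4) and challenged homozygous mutants (n = 4). The series title names Ifit2, an interferon-induced gene, and signalling by interferon, and the stated design sets mutants against wild types with and without challenge. The dose, route and schedule of the challenge are not given in the sources used here. An array detected between 39.8% and 53.6% of the 25697 probes, and its mean signal lay between 319.9 and 666 intensity units. Challenged arrays were dimmer than unchallenged ones, with a mean signal of 445 ± 60.9 (SD, n = 8) against 615 ± 55.6 (SD, n = 7; exact two-sided permutation p = 0.000466). They also detected fewer probes, 46.1 ± 3.12% (SD, n = 8) against 51.6 ± 1.74% (SD, n = 7; exact two-sided permutation p = 0.000777). Within wild types the exact two-sided permutation p was 0.0857 for mean signal and 0.0571 for detection. Within mutants it was 0.0286 and 0.0571. Arrays of the same group correlated at 0.902 to 0.993 and arrays of different groups at 0.861 to 0.991, and the number of arrays limits the precision of every comparison.

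Ifit2 was the first gene examined, because it checks the genotype labels. Both Ifit2 probes were detected on all 8 wild-type arrays and on 0 of the 7 mutant arrays. Probe ILMN_2981169 stood at a log2 intensity of 8.26 ± 0.03 (SD, n = 4) in unchallenged wild types and 5.07 ± 0.16 (SD, n = 3) in unchallenged mutants, and at 7.94 ± 0.19 (SD, n = 4) and 5.35 ± 0.42 (SD, n = 4) in the challenged groups. It was at least 6.49-fold lower in unchallenged mutants and at least 3.97-fold lower in challenged mutants. Probe ILMN_2981167 was at least 4.59-fold and at least 1.89-fold lower in the same comparisons. The exact two-sided permutation p was 0.0286 for each probe in each state, the smallest value that these group sizes allow. Where the probes lie relative to the mutation is not given in the sources used here. Between challenged and unchallenged wild types the Ifit2 probes gave different results: ILMN_2981167 fell by 0.89 ± 0.15 on the log2 scale (SE; limma adjusted p = 0.00149), and ILMN_2981169 differed by -0.32 ± 0.17 (adjusted p = 0.210). The design text calls the mutants male, yet both probes of Xist, the RNA that coats the inactive X chromosome of females, were detected on all 15 arrays. Of the Y-linked genes, Eif2s3y was detected on 1 array, Uty on 2 and Kdm5d on 0.

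**Figure D1:**
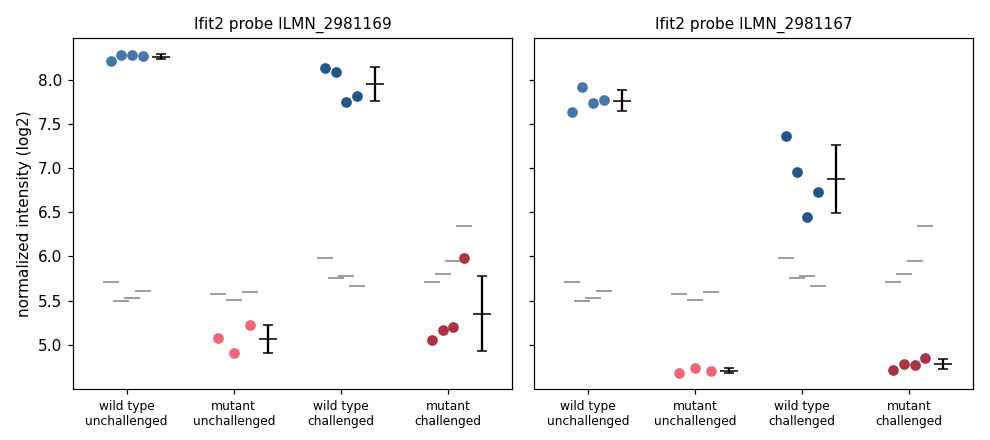
Normalized log2 intensity of both Ifit2 probes on each of the 15 arrays (points), with the group mean and SD (black) and the lowest detected intensity of each array (grey dashes). Wild-type arrays lie above the grey dashes and mutant arrays below, with group means of 8.26 and 7.94 against 5.07 and 5.35 for probe ILMN_2981169.

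What the challenge changed in wild-type lung was asked by setting challenged against unchallenged wild types. Many genes of the lists for mucus-producing airway cells and for alternatively activated macrophages rose. So did part of the chemokine, neutrophil and eosinophil genes and most cell-cycle genes, whereas part of the endothelial and circadian clock genes fell. Which cells carried the genes of these lists cannot be told from whole-lung RNA. Camera called each of these lists at its preset correlation and none with an estimated correlation (adjusted p = 0.211 to adjusted p = 0.270), and the clock call ended with median scaling as well. Fry called 19 of the 33 lists tested in this comparison. Clca1, a secreted protein of goblet cells, rose 119-fold (log2 6.89 ± 1.01, SE; limma adjusted p = 0.000530), from 7.32 ± 2.04 to 14.21 ± 0.55 (SD, n = 4 in each group), and without unchallenged wild type 1 its log2 change was 7.87. Rnase2a, an eosinophil-associated ribonuclease, was detected on 0 of 4 unchallenged and 4 of 4 challenged arrays and was at least 63.5-fold higher (adjusted p = 7.00e-06). Chil4, a chitinase-like protein, rose 70.6-fold (log2 6.14 ± 0.48, SE), Retnla 34.8-fold (5.12 ± 0.47), the anion exchanger gene Slc26a4 30.3-fold (4.92 ± 0.40) and the macrophage elastase gene Mmp12 23.1-fold (4.53 ± 0.50). Angptl4, an inhibitor of lipoprotein lipase, fell by 2.79 ± 0.21 on the log2 scale, the paraoxonase gene Pon1 by 2.28 ± 0.28, the potassium channel subunit gene Kcne2 by 1.97 ± 0.29 and the xenobiotic-metabolizing Cyp2a5 by 1.86 ± 0.35. For each of these genes all 4 challenged arrays lay beyond all 4 unchallenged ones, a condition of the rule that picked them.

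By gene list, 13 of 15 goblet and mucus genes rose (13 adjusted over the list alone) and 0 fell. Muc5ac, a gel-forming mucin, was at least 15.4-fold higher and the trefoil peptide gene Tff1 5.34-fold higher (log2 2.42 ± 0.26, SE). The list's camera adjusted p was 1.93e-19 with the preset correlation, and its adjusted p = 0.211 with an estimated correlation. Of 17 alternative macrophage genes 13 rose and 0 fell (14 and 0 adjusted over the list alone), among them Chil4, Retnla, Mmp12 and the chitinase gene Chia1 (6.15-fold). Camera gave an adjusted p of 9.41e-17, and adjusted p = 0.211 with an estimated correlation. Of 16 proliferation genes 13 rose and 0 fell (14 and 0 adjusted over the list alone), including thymidine kinase Tk1 (3.77-fold) and the replication licensing gene Mcm5 (2.59-fold). The list passed with a camera adjusted p of 2.27e-12, or adjusted p = 0.211 with an estimated correlation.

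Of 19 genes of the response to TNF or lipopolysaccharide 11 rose and 0 fell (11 and 1 adjusted over the list alone). The acute-phase gene Saa3 was 20.7-fold higher (log2 4.37 ± 0.61, SE), the monocyte attractant Ccl7 10.4-fold (3.37 ± 0.35) and the neutrophil attractant Cxcl1 8.74-fold (3.13 ± 0.43). The camera adjusted p was 1.09e-06, and adjusted p = 0.211 with an estimated correlation. Of 9 type 2 cytokine and chemokine genes 5 rose (5 adjusted over the list alone), with Ccl8 17.4-fold, Ccl17 6.37-fold and the eosinophil attractant Ccl11 3.96-fold higher. That list had a camera adjusted p of 0.000834, and adjusted p = 0.211 with an estimated correlation. Its entries Il4, Il5, Il13 and Il25 were on the array but did not pass the detection filter. The eosinophil list had 2 of 4 genes higher (3 adjusted over the list alone; camera adjusted p = 0.000785, and adjusted p = 0.211 with an estimated correlation). The eosinophil entries Epx, Siglecf, Ccr3 and Ear6 were on the array but did not pass the detection filter. Prg2, major basic protein of eosinophil granules, rose 2.53-fold, a call that ended without unchallenged wild type 4 (log2 1.23, adjusted p = 0.0563). The neutrophil list had 5 of 10 higher (5 adjusted over the list alone), with Retnlg 7.15-fold and the calprotectin subunit gene S100a9 2.95-fold higher. Its camera adjusted p was 3.39e-05, and adjusted p = 0.270 with an estimated correlation. Of 14 T cell genes 4 rose (4 adjusted over the list alone), with the inhibitory receptor gene Ctla4 3.49-fold and the regulatory T cell factor Foxp3 2.04-fold higher (camera adjusted p = 0.00216, and adjusted p = 0.416 with an estimated correlation).

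Of 37 interferon-stimulated genes 10 rose, 0 fell and 27 did not pass (10 and 0 adjusted over the list alone), with a list median of 0.18 log2. Cxcl10 was 3.10-fold higher and the nucleic acid sensor Zbp1 at least 1.54-fold. Ifit3, a relative of Ifit2 and its neighbour on chromosome 19, was 1.53-fold higher (log2 0.61 ± 0.12, SE). The list's camera adjusted p was 0.00216, and adjusted p = 0.370 with an estimated correlation. With median scaling the Ifit3 change no longer passed (adjusted p = 0.183). Antigen presentation genes of dendritic cells rose in 5 of 12 cases and 0 fell (9 and 1 adjusted over the list alone), with the integrin gene Itgax 2.80-fold and the protease gene Ctss 2.94-fold higher. Camera gave them an adjusted p of 0.000189, and adjusted p = 0.357 with an estimated correlation. Of 14 MHC class I genes 6 rose (6 adjusted over the list alone; camera adjusted p = 0.00216, and adjusted p = 0.375 with an estimated correlation). Endothelial genes fell in 8 of 13 cases and rose in 0 (9 lower adjusted over the list alone), with the receptor gene Tek at -1.17 ± 0.24 log2 (SE). Their camera adjusted p was 1.64e-05, and adjusted p = 0.211 with an estimated correlation. Of 12 clock genes 6 fell and 0 rose (6 adjusted over the list alone), with Per1 at -1.89 ± 0.39 and Per3 at -1.03 ± 0.22 log2 (camera adjusted p = 0.0209, and adjusted p = 0.211 with an estimated correlation; 0.0526 with median scaling and 0.0686 with mean signal as a covariate). Of 10 genes induced by glucocorticoids or hypoxia 2 rose and 5 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.0169, and adjusted p = 0.357 with an estimated correlation), with Tsc22d3 at -1.67 ± 0.29. Immediate early and stress genes rose in 6 of 14 cases and fell in 2 (7 and 5 adjusted over the list alone; camera adjusted p = 0.0252, and adjusted p = 0.357 with an estimated correlation), with Atf3 2.05-fold and Egr1 2.08-fold higher. The glucocorticoid call ended with median scaling (0.0710), with rank-based camera (0.0722), when only these groups were fitted (0.0910) and without unchallenged mutants 1 and 3 (0.0717). The immediate early call ended in 9 of 36 alternatives: besides the estimated correlation, median scaling (0.0869), cyclic loess (0.0514), array weights (0.113), rank-based camera (0.253), only these groups (0.0669), the pancreas level as a covariate (0.0679), and fits without challenged wild type 4 alone (0.0562) or together with challenged mutants 1 and 4 (0.0898). Club cell genes of the small airways went both ways, with 2 of 11 higher and 3 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.912), and Cyp2f2 fell by 1.08 ± 0.28. None of 11 ciliated cell genes passed (0 adjusted over the list alone; camera adjusted p = 0.679).

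Pnliprp1, a pancreatic lipase-related gene, was higher in challenged wild types (log2 5.13 ± 1.68, SE; adjusted p = 0.0413), but the challenged arrays ranged from 7.65 to 14.57. Of 32 alternative fits it passed in 18, and its log2 change was 3.97, 4.23, 6.04 and 6.27 without challenged wild type 1, 2, 3 and 4. Without background correction the log2 changes were smaller, as 4.24 for Chil4, 5.84 for Clca1 and 1.15 for Tff1. Of the unchallenged arrays 1 of 4 detected Chil4 and Prg2, 2 detected Cxcl10, Ccl7, Cxcl1, Ccl8 and Tff1, and 3 detected Saa3 and Ctla4, while 1 of 4 challenged arrays detected Kcne2 and Per3. Over all 14396 probes tested, 1411 rose and 1829 fell, corresponding to 2712 genes. The groups did not overlap for 28.8% of probes, against 2.86% by chance. The count of 3240 was 2106 without unchallenged wild type 2, 2127 without unchallenged wild type 3, 5410 with array weights, 2068 with a 1.5-fold minimum and 1472 with the array's mean signal as a covariate, under which S100a9, Foxp3, Tek, Per3 and Prg2 no longer passed. Challenged wild types were dimmer on average, so that covariate cannot fully tell brightness from challenge. Scaling by medians moved the median of all probes to -0.24 and the split to 648 higher and 3780 lower, while the direction of each list above, taken relative to that shift, stayed the same.

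**Figure D2:**
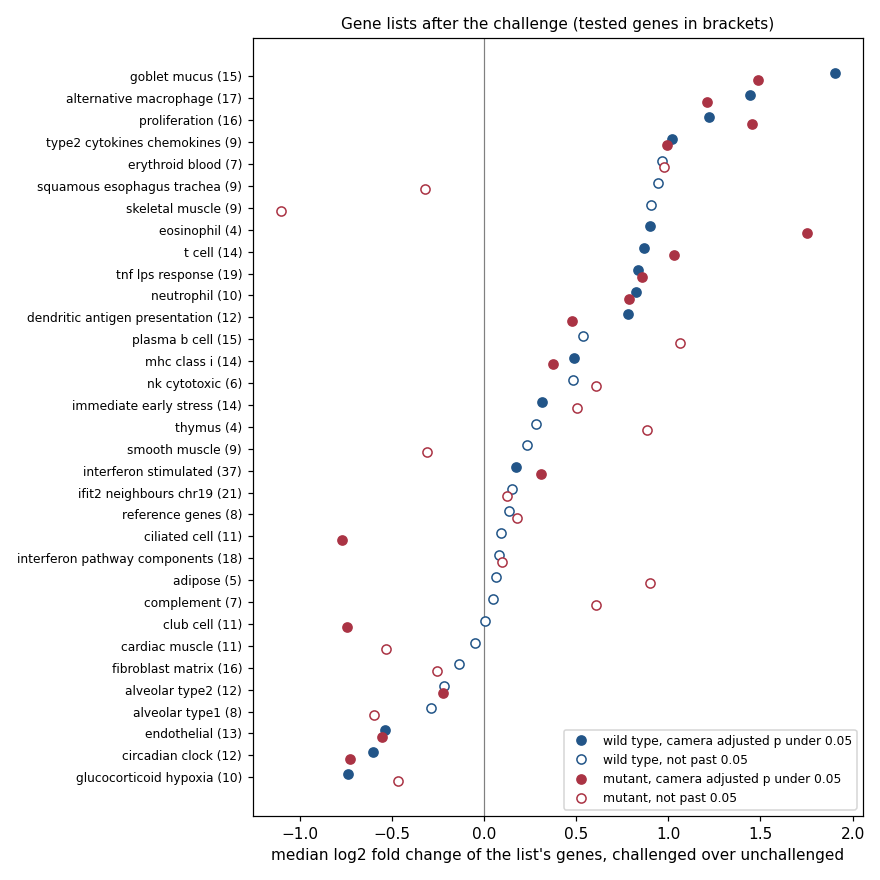
Median log2 fold change of the tested genes of each fixed list, challenged over unchallenged, in wild types (blue) and mutants (red). Filled points mark lists with a camera adjusted p under 0.05 at the preset correlation, a call that 0 lists kept with an estimated correlation. Goblet and mucus genes had medians of 1.91 and 1.49, and endothelial genes of -0.54 and -0.55.

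The challenge was then examined in the mutants (n = 4 challenged, n = 3 unchallenged). Most tested genes of the eosinophil, mucus, macrophage, chemokine and proliferation lists rose in mutant lung too. Part of the club, ciliated, endothelial and clock genes fell. Camera called these lists at its preset correlation and none with an estimated correlation (adjusted p = 0.297 to adjusted p = 0.479), and the club and clock calls ended with median scaling as well (0.285 and 0.0647). Fry called 25 of the 33 lists tested here. Rnase2a rose 54.1-fold (log2 5.76 ± 0.57, SE; limma adjusted p = 6.50e-05), Chil4 21.1-fold (4.40 ± 0.51), arginase Arg1 20.2-fold (4.34 ± 0.46), Saa3 20.1-fold (4.33 ± 0.65), the ion transport regulator Fxyd4 13.5-fold (3.76 ± 0.23) and Slc26a4 12.8-fold (3.68 ± 0.43). Clca1 rose 10.9-fold (log2 3.45 ± 1.09; adjusted p = 0.0279), a call that ended without unchallenged mutant 2 (log2 1.86, adjusted p = 0.162) or challenged mutant 3 (log2 3.33, adjusted p = 0.0557), and its log2 change was 4.10 without unchallenged mutant 1 and 4.39 without unchallenged mutant 3. Without unchallenged mutant 2 the log2 change was 4.92 for Rnase2a, 3.70 for Saa3 and 2.91 for Slc26a4, while Saa3 was at 5.06 without unchallenged mutant 1 and Rnase2a at 6.69 without unchallenged mutant 3. Pon1 fell by 2.73 ± 0.30 on the log2 scale, the axonemal gene Spag6l by 2.39 ± 0.50 and the hypoxia factor Epas1 by 2.28 ± 0.24, and the ciliary anchoring protein gene Akap14 was at least 3.50-fold lower. Of the 3 unchallenged arrays 2 detected Rnase2a, Chil4 and Muc5ac and 1 detected Fxyd4, and 3 of 4 challenged arrays detected Spag6l.

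Of 15 goblet and mucus genes 11 rose and 0 fell (11 and 0 adjusted over the list alone), with Muc5ac 7.31-fold higher (log2 2.87 ± 0.46, SE). The camera adjusted p was 2.76e-08, and adjusted p = 0.297 with an estimated correlation. Alternative macrophage genes rose in 12 of 17 cases (12 adjusted over the list alone), with Retnla 8.17-fold higher (camera adjusted p = 2.07e-07, and adjusted p = 0.339 with an estimated correlation). The log2 change of Retnla, 3.03, was 2.13 without unchallenged mutant 2 and 3.62 without unchallenged mutant 3. In the proliferation list 15 of 16 genes rose (16 adjusted over the list alone), with Tk1 4.08-fold and Mcm5 3.33-fold higher (camera adjusted p = 9.36e-13, and adjusted p = 0.316 with an estimated correlation). Challenged mutant 1, highest of its group on the thymus list, stood at 2.28 on the proliferation list relative to unchallenged wild types, against 1.55 to 1.71 on the other challenged mutants. The TNF and lipopolysaccharide list had 11 of 19 higher and 1 lower (11 and 2 adjusted over the list alone; camera adjusted p = 9.17e-05, and adjusted p = 0.339 with an estimated correlation), with Ccl7 8.22-fold higher. Type 2 genes rose in 6 of 9 cases (6 adjusted over the list alone; camera adjusted p = 0.000515, and adjusted p = 0.297 with an estimated correlation). Ccl11 was 5.96-fold and the eosinophil attractant Ccl24 at least 5.29-fold higher. Eosinophil genes rose in 3 of 4 cases (3 adjusted over the list alone) and neutrophil genes in 4 of 10 (7 adjusted over the list alone). Their camera adjusted p values were 0.00292 and 0.000259, and adjusted p = 0.297 and adjusted p = 0.339 with an estimated correlation.

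Interferon-stimulated genes rose in 12 of 37 cases and fell in 0, while 25 did not pass (12 and 0 adjusted over the list alone), with a list median of 0.31 log2. Irf7, a transcription factor of the interferon response, was 2.15-fold higher (log2 1.10 ± 0.20, SE), Ifi27l2a 2.06-fold (1.04 ± 0.19) and Zbp1 1.97-fold (0.98 ± 0.16). The camera adjusted p was 0.000356, and adjusted p = 0.348 with an estimated correlation. T cell genes rose in 6 of 14 cases (7 adjusted over the list alone; camera adjusted p = 0.00460, and adjusted p = 0.479 with an estimated correlation). Relative to unchallenged wild types challenged mutant 1 stood at 2.51 on the T cell list and 3.69 on the thymus list, against 0.69 to 1.66 and 0.28 to 0.83 on the other challenged mutants, and the T cell call ended without challenged wild type 4 and challenged mutants 1 and 4 (0.107). In the B and plasma cell list 6 of 15 genes rose (10 adjusted over the list alone), including the B cell receptor component Cd79a (3.58-fold), without the list passing (camera adjusted p = 0.0567). The Cd79a call ended without unchallenged mutant 2 (log2 1.30, adjusted p = 0.115). Club cell genes fell in 7 of 11 cases and rose in 1 (7 and 1 adjusted over the list alone), with Cyp2f2 at -1.96 ± 0.30 and the carbonyl reductase Cbr2 at -1.44 ± 0.19 log2 (SE). Of 11 ciliated cell genes 6 fell and 0 rose (6 adjusted over the list alone), including Mlf1 at -0.93 ± 0.24, which no longer passed without unchallenged mutant 2 (log2 -0.86, adjusted p = 0.0529). The camera adjusted p was 0.00460 for the club and 0.0175 for the ciliated list, and adjusted p = 0.479 for each with an estimated correlation. With median scaling the club list no longer passed (adjusted p = 0.285), and both calls ended without challenged wild type 4 and challenged mutants 1 and 4 (0.0531 and 0.0697). Endothelial genes fell in 8 of 13 cases (8 adjusted over the list alone; camera adjusted p = 0.000356, and adjusted p = 0.339 with an estimated correlation), with Tek at -1.65 ± 0.26. Clock genes fell in 6 of 12 cases (7 adjusted over the list alone; camera adjusted p = 0.0175, and adjusted p = 0.297 with an estimated correlation), with Per2 at -1.40 ± 0.25. The clock list did not pass with median scaling (adjusted p = 0.0647) or with mean signal as a covariate (0.136). Dendritic antigen presentation genes rose in 4 of 12 cases and fell in 1 (4 and 1 adjusted over the list alone), and MHC class I genes rose in 6 of 14 (6 adjusted over the list alone). Each list had a camera adjusted p of 0.0402, and adjusted p = 0.479 with an estimated correlation. The dendritic call ended without unchallenged mutant 2 (0.179), challenged wild type 1 (0.0614), challenged mutant 3 (0.0566) or 4 (0.0779), or challenged wild type 4 and challenged mutants 1 and 4 (0.131), and with array weights (0.102), the authors' series matrix values (0.0541) and only these groups (0.0712), and its sign turned with mean signal as a covariate. The class I call ended without unchallenged mutant 2 (0.186) or 3 (0.0547), challenged mutant 2 (0.0545), or challenged wild type 4 and challenged mutants 1 and 4 (0.0713), with the mean of a gene's probes (0.0887), and with mean signal (0.814) or skeletal muscle level (0.0614) as a covariate. Alveolar type 2 genes fell in 4 of 12 cases (4 adjusted over the list alone; camera adjusted p = 0.0443, and adjusted p = 0.479 with an estimated correlation), and passed in 21 of 36 alternatives. Besides the estimated correlation, that call ended with median scaling (0.857), cyclic loess (0.279), the authors' series matrix values (0.102), array weights (0.0848), the replicate number as a block (0.0664), the pancreas level as a covariate (0.0655), a strict filter (0.0650) and only these groups (0.0546). It also ended without unchallenged mutant 1 alone (0.132) or together with 3 (0.152), challenged wild type 1 (0.0567), challenged mutant 1 (0.0654) or 2 (0.0650), or challenged wild type 4 and challenged mutants 1 and 4 (0.107).

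In mutants 1944 probes rose and 2448 fell, corresponding to 3641 genes, and the groups did not overlap for 38.1% of probes against 5.71% by chance. Pnliprp1 was 32.3-fold higher (adjusted p = 0.0495), with challenged arrays from 7.47 to 14.99, and its log2 change was 4.27, 3.63, 6.02 and 6.14 without challenged mutant 1, 2, 3 and 4. The challenged mutant arrays were all dimmer than the unchallenged ones, and of the unchallenged mutants arrays 1 and 3 had raised levels of goblet and macrophage genes. The count of 4392 was 2310 without unchallenged mutant 2, 1665 without unchallenged mutants 1 and 3 (a fit that keeps 1 unchallenged mutant, assumed to vary like the other groups), 2531 when only these 2 groups were fitted and 563 with the array's mean signal as a covariate, under which Clca1, Retnla, Irf7, Ifi27l2a, Cd79a, Spag6l, Mlf1, Tek and Per2 no longer passed. Mean signal separated these groups fully, so as a covariate it cannot tell brightness from challenge. Scaling by medians moved the median of all probes to -0.42 and gave 624 higher and 6046 lower. The challenge effects of both genotypes shared 1071 higher and 1436 lower probes, where independent lists would share 191 and 311, and 0 probes were called in opposite directions. The comparisons share no arrays, but they come from the same model, with a spread estimated over all 15 arrays. Challenged arrays were also dimmer on average in both genotypes, so independent lists are not a full reference for this overlap.

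Whether the mutation alters the unchallenged lung was asked by setting 3 unchallenged mutants against 4 unchallenged wild types. Ifit2 was the only gene past the threshold: its probes, detected on 0 mutant arrays, were at least 6.49-fold and at least 4.59-fold lower (limma adjusted p = 4.75e-07 and 2.82e-07). Goblet, macrophage and antigen presentation genes had higher means in mutants without passing, and the excess came from mutants 1 and 3. On the scale of the goblet list's mean log2 level over unchallenged wild types, mutants 1 and 3 stood at 0.96 and 0.98 and mutant 2 at -0.10. For the alternative macrophage list they stood at 1.13 and 1.11 and mutant 2 at -0.00335. Retnla had a log2 difference of 2.00 ± 0.51 (SE; adjusted p = 0.999), the chitinase-like Chil3 1.12 ± 0.28 (adjusted p = 0.999), Slc26a4 1.71 ± 0.43 (adjusted p = 0.999) and Clca1 2.83 ± 1.09 (adjusted p = 1).

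**Figure D3:**
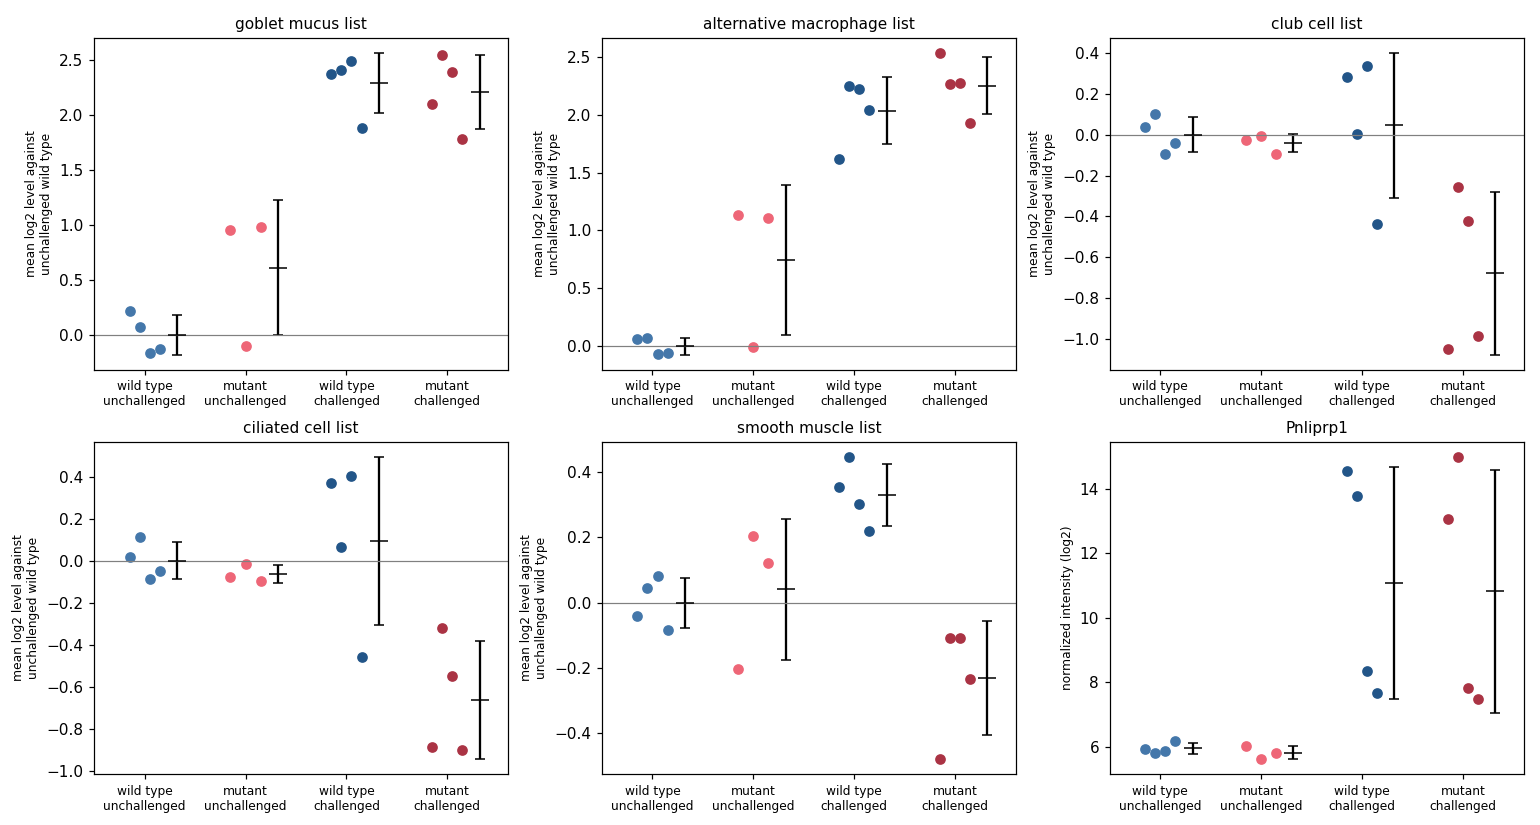
Mean log2 level of 5 gene lists relative to unchallenged wild types, and log2 intensity of Pnliprp1, on each of the 15 arrays (points), with group mean and SD (black). Unchallenged mutants 1 and 3 stand at 0.96 and 0.98 on the goblet list, challenged mutants average -0.68 on the club cell list, and Pnliprp1 spans 7.47 to 14.99 on challenged arrays.

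None of the members of the 33 lists tested with camera, which do not hold Ifit2, passed the threshold over all probes in the unchallenged comparison, although camera with the preset correlation called 13 lists higher and 2 lower. Alternative macrophage genes were higher in 15 of 17 cases (5 adjusted over the list alone; camera adjusted p = 3.66e-15, and adjusted p = 0.184 with an estimated correlation). Goblet genes were higher in 14 of 15 cases (1 adjusted over the list alone; camera adjusted p = 1.11e-07, and adjusted p = 0.184 with an estimated correlation). Interferon-stimulated genes were higher in 30 of 37 cases with a median of 0.22 log2 (1 adjusted over the list alone; camera adjusted p = 2.92e-09, and adjusted p = 0.184 with an estimated correlation). Ifit3 had a log2 difference of 0.54 ± 0.13 (SE; adjusted p = 0.999), and Zbp1, detected on 0 of 4 wild-type and 3 of 3 mutant arrays, was at least 1.14-fold higher (adjusted p = 1). Proliferation genes were higher in 15 of 16 cases (0 adjusted over the list alone; camera adjusted p = 2.19e-08, and adjusted p = 0.246 with an estimated correlation). Dendritic antigen presentation genes were higher in 11 of 12 (0 adjusted over the list alone; camera adjusted p = 2.19e-08, and adjusted p = 0.184 with an estimated correlation), with Ctss at 0.79 ± 0.28 and Cd74 at 0.66 ± 0.26 (adjusted p = 1 for each). Fry, which tests whether the genes of a list move on balance in a single direction, called 0 lists. At an unadjusted p under 0.05 there were 375 probes, fewer than the 0.05 share of the 14396 probes tested that chance would give on average. The groups did not overlap for 7.55% of probes, against 5.71% by chance. Leaving out mutant 2 raised the count from 2 to 36 probes. With mutants 1 and 3 left out for their high levels, mutant 2 alone remained and was assumed to vary like the other groups. In that fit 6 lists passed, and 9 of the 15 lists had the opposite sign, the T cell list being the 1 of these 9 that passed (adjusted p = 0.0170).

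Whether the challenged lung differs by genotype was asked by setting 4 challenged mutants against 4 challenged wild types. Besides Ifit2 (at least 3.97-fold lower; limma adjusted p = 5.58e-06), the genes past the threshold included Akap14, Cfap206, Pifo, Cbr2, Actg2 and Acta2, all lower in mutants. The 4 higher probes belonged to Ifi27l2a, Oas1g, Atad5 and Ccne2. Akap14 was detected on 4 of 4 wild-type and 0 of 4 mutant arrays and was at least 1.93-fold lower (adjusted p = 0.00644). The ciliary gene Cfap206 was at least 2.03-fold lower (adjusted p = 0.0424) and the kinase gene Nek5 at least 1.35-fold lower (adjusted p = 0.0352). Pifo, a gene of cilium formation, fell by 1.20 ± 0.22 on the log2 scale, the tight junction gene Cldn10 by 1.12 ± 0.20, Cbr2 by 0.99 ± 0.18 and haptoglobin Hp by 0.93 ± 0.15. The smooth muscle actin genes Actg2 and Acta2 fell by 0.79 ± 0.14 and by 0.65 ± 0.11. Ifi27l2a rose 2.07-fold (log2 1.05 ± 0.18; adjusted p = 0.0398), the replication factor gene Atad5 1.81-fold (0.86 ± 0.15; adjusted p = 0.0398), and the cyclin gene Ccne2 was at least 1.31-fold higher (adjusted p = 0.0352). The dimmer Oas1g probe, chosen after its values were seen, had a log2 difference of 1.10 ± 0.15 (adjusted p = 0.00644).

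Club cell genes were lower in 11 of 11 cases, 3 of them past the threshold over all probes and 7 adjusted over the list alone (camera adjusted p = 1.50e-10, and adjusted p = 0.192 with an estimated correlation). Ciliated cell genes were lower in 11 of 11, with 0 past the threshold over all probes and 10 adjusted over the list alone (camera adjusted p = 1.50e-10, and adjusted p = 0.192 with an estimated correlation). Smooth muscle genes were lower in 9 of 9, with 2 past the threshold and 4 adjusted over the list alone (camera adjusted p = 1.34e-09, and adjusted p = 0.164 with an estimated correlation). On single arrays the genotypes overlapped for the club and ciliated lists: relative to unchallenged wild types, challenged wild type 4 stood at -0.44 and -0.46 and challenged mutant 2 at -0.26 and -0.32. For the smooth muscle list all challenged wild types lay above all challenged mutants. Interferon-stimulated genes were higher in 34 of 37 cases with a median of 0.27 log2, 1 past the threshold and 8 adjusted over the list alone (camera adjusted p = 3.26e-10, and adjusted p = 0.192 with an estimated correlation). Ifit3 had a log2 difference of 0.64 ± 0.12 (SE; adjusted p = 0.0585), the oligoadenylate synthetase-like Oasl1 of 0.78 ± 0.16 (adjusted p = 0.0746) and the brighter Oas1g probe of 0.69 ± 0.17 (adjusted p = 0.106). Fry called these 4 lists, with adjusted p from 0.00336 to 0.0242. Proliferation genes were higher in 16 of 16 cases, 0 past the threshold and 11 adjusted over the list alone (camera adjusted p = 1.50e-10, and adjusted p = 0.266 with an estimated correlation; fry adjusted p = 0.0672), with Mcm5 and Mcm2 each at a log2 difference of 0.65 ± 0.19. Challenged mutant 1, which stood apart on the thymus list (3.69, against 0.28 to 0.83 on the other challenged mutants), also had the highest proliferation level (2.28, against 1.55 to 1.71 on the other challenged mutants and 0.72 to 1.53 on challenged wild types). The goblet list did not pass (median -0.10 log2, 0 adjusted over the list alone; camera adjusted p = 0.876).

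Markers of neighbouring tissue were also compared between the challenged groups, and fry called none of the adipose, thymus, T cell, type 2, TNF and complement lists there (adjusted p from 0.1001 to 0.290). Adipose genes were higher in 5 of 5 cases with a median of 1.78 log2 (0 past the threshold, 3 adjusted over the list alone; camera adjusted p = 0.00112, and adjusted p = 0.300 with an estimated correlation). Ucp1, the uncoupling protein of brown fat, was detected on 2 of 4 wild-type and 4 of 4 mutant arrays and had a log2 difference of 2.94 ± 0.87 (SE; adjusted p = 0.170) and the lipid droplet gene Cidec of 1.78 ± 0.52 (adjusted p = 0.168). Of 4 thymus genes all had higher means in mutants (0 adjusted over the list alone; camera adjusted p = 0.0287, and adjusted p = 0.488 with an estimated correlation). Without challenged mutant 1, where Rag1 stood at 10.65 against 5.38 on the nearest array of its group, the list's adjusted p was 0.364, and without challenged wild type 1 or 4 it was 0.0689 or 0.0501. It was 0.598 without challenged wild type 4 and challenged mutants 1 and 4, 0.0587 with array weights and 0.0618 with skeletal muscle level as a covariate. T cell genes were higher in 14 of 14 cases (0 adjusted over the list alone; camera adjusted p = 0.00393, and adjusted p = 0.493 with an estimated correlation), with an adjusted p of 0.175 without challenged mutant 1 and 0.738 without challenged wild type 4 and challenged mutants 1 and 4. Type 2 genes were higher in 9 of 9 and TNF and lipopolysaccharide genes in 15 of 19 (1 adjusted over the list alone in each). Their camera adjusted p values were 0.00573 and 0.00747, and adjusted p = 0.266 and adjusted p = 0.493 with an estimated correlation. The type 2 call ended without challenged mutant 1 (0.0600) and with a strict filter (0.0606), and the TNF call without challenged wild type 1 (0.0806) or challenged mutant 2 (0.0919) and with no detection filter (0.0853). Complement genes were higher in 4 of 7 cases (0 past the threshold, 2 adjusted over the list alone; camera adjusted p = 0.0432, and adjusted p = 0.345 with an estimated correlation). That call ended without challenged wild type 1 (0.163) or 4 (0.0572) or challenged mutant 1 (0.0721), 2 (0.0919) or 3 (0.123), and with rank-based camera (0.0687). Skeletal muscle genes ranged from -3.52 to 2.68 log2 across the challenged arrays relative to unchallenged wild types, without a group difference that passed (0 of 9 adjusted over the list alone; camera adjusted p = 0.115).

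In all, 25 probes of 21 genes passed, 4 higher and 21 lower, with 1828 probes at an unadjusted p under 0.05, and 4.16% of probes did not overlap against 2.86% by chance. Leaving out challenged wild type 4 gave 192 probes and leaving out challenged mutant 2 gave 130, while leaving out any other array gave 7 to 11. The count was 12 with cyclic loess, 15 with no detection filter, 16 with the replicate number as a block, 44 with a strict filter, 8 with array weights, 9 with mean signal as a covariate and 2 when only these groups were fitted. Akap14 passed in 31 of 32 alternative fits, with adjusted p from 0.00233 to 0.180, and the other genes named by their brightest probe, besides Ifit2, passed in at most 16. Scaling by medians gave 1 higher and 74 lower, with the median of all probes at -0.17.

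Whether the response to challenge differs between genotypes was tested as the interaction. By limma 0 of 14396 probes passed and the lowest adjusted p was 0.950. An unadjusted p under 0.05 was found for 590 probes, fewer than the 0.05 share that chance would give on average. Cyclic loess gave 1 probe, leaving out unchallenged mutant 2 gave 8, and the other fits gave 0. The genes with the smallest p were the protease inhibitor Spink2 (log2 1.06 ± 0.21, SE), the Wnt antagonist Sfrp2 (1.18 ± 0.24), Angptl4 (1.34 ± 0.30), Lrrn4 (0.95 ± 0.22) and Akap14, each with an adjusted p of 0.950. No size is given for Akap14, since challenged mutants did not measure it above background. Smooth muscle, club and ciliated genes had interaction medians of -0.71, -0.79 and -0.64 log2 (4, 4 and 1 lower adjusted over the list alone), with Actg2 at -0.78 ± 0.21, Hp at -0.79 ± 0.22 and Mlf1 at -1.19 ± 0.33. Their camera adjusted p values were 9.10e-09, 1.93e-08 and 1.09e-08, and adjusted p = 0.135, adjusted p = 0.270 and adjusted p = 0.270 with an estimated correlation. The goblet and macrophage lists were lower by camera as well (adjusted p = 0.000912 and 0.00439; 0 adjusted over the list alone), with adjusted p = 0.814 for each with an estimated correlation. Both lists had the opposite sign, without passing, in the fit that keeps only unchallenged mutant 2 of its group (adjusted p = 0.813 and 0.0525). The macrophage call ended without unchallenged mutant 1 (0.138) or 3 (0.0778) alone, with median scaling (0.0543), with mean signal as a covariate (0.198) and without challenged wild type 4 and challenged mutants 1 and 4 (0.0905). Fry called 0 lists.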

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

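The tests of a wrong label, of mixed RNA, of a shared genotype effect, of pancreatic RNA, of airway lining and of chance among the challenged mice were chosen after the results were seen.

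Of 408 groups of 4 arrays examined over 136 values, 25 held an array far from the others, or 6.13%, where chance gives about 5%. The distance is the gap to the nearest array as a share of the group's range. Among sample-wide values, unchallenged wild type 1 had the lowest mean signal (0.856), the highest natural killer level (0.855) and the lowest skeletal muscle level (0.839). Challenged wild type 2 had the lowest natural killer level (0.861), challenged wild type 3 the lowest level of glucocorticoid and hypoxia genes (0.901), challenged wild type 1 the lowest level of reference genes (0.892) and challenged mutant 1 the highest thymus level (0.838).

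Single genes gave the others. Ifit2 probe ILMN_2981169 was highest on challenged mutant 4 (0.838), where it was still undetected. On challenged wild type 4 Clca1 (1) and Muc5ac (0.913) were lowest, on challenged wild type 3 Cxcl10 was highest (0.870), and on challenged wild type 2 Ctla4 was lowest (0.877) and Sftpd highest (1). Eng was highest on challenged wild type 1 (0.903). Cxcl1 was highest on challenged mutant 2 (0.907) and Ch25h lowest on challenged mutant 4 (0.839). On challenged mutant 1 Sec14l3 was lowest (0.874), while Ucp1 (0.876) and Rag1 (0.961) were highest. On unchallenged wild type 1 Tek was lowest (0.922), with Epas1 (0.850) and Tekt1 (0.840) highest, Cyp2f2 (1) and Cfb (0.890) were highest on unchallenged wild type 2, and Prf1 was lowest on unchallenged wild type 4 (0.940). A share of 1 arises where quantile normalization gives tied values.

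The challenge effect differed between genotypes by camera at the preset correlation for 8 lists: goblet (adjusted p = 0.000912), alternative macrophage (0.00439), alveolar type 2 (0.0166), club (1.93e-08), ciliated (1.09e-08), smooth muscle (9.10e-09), skeletal muscle (0.0112) and proliferation genes (0.0372). With an estimated correlation and with fry 0 of them passed.

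Unchallenged mutants 1 and 3 carried high levels of genes that the challenge raised in wild types. Relative to the wild-type challenge effect their responses were 0.41 and 0.34, against 1.11 to 1.19 on challenged mutants, which argues against challenged mice under a wrong label (0.414). An effect of the genotype shared by all 3 cannot be told apart from differences between these mice, because unchallenged mutant 2 alone decides (-0.0360, within the -0.05 to 0.11 of unchallenged wild types) and the pattern was noticed from it. Challenged RNA mixed into the arrays cannot be told apart from no mixing, because with no mixture 3.37% of 326 probes lay outside the band on array 3, although 11.0% did on array 1. A biological difference between these mice stays open and untested.

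Exocrine pancreas genes such as Pnliprp1 were high on some challenged arrays of both genotypes. The islet hormone gene Ins2 was detected on 7 of 8 challenged arrays and on 0 of 7 unchallenged ones, consistent with pancreatic RNA in the challenged samples. In all 3 islet hormone genes (Ins2, Gcg and Pyy) were detected on at least 2 challenged and no unchallenged arrays, which argues against induction of digestive enzymes in lung cells. Beyond challenged mutant 2 this rests mainly on Ins2. Gcg and Pyy stood at 10.82 and 9.00 there and at most at 6.06 and 5.96 on other challenged arrays. Iapp was detected on 7 challenged and 7 unchallenged arrays, Sst on 1 challenged array and Ppy on 0. Of salivary gland genes 0% were higher on all challenged arrays, but only 2 were tested, so that test could not decide. Challenged wild types 1 and 2 and challenged mutants 1 and 2 held exocrine genes 4.02 to 8.18 log2 above unchallenged arrays. Ins2 stood at 9.30 to 14.12 on them, against 4.87 to 5.38 on unchallenged arrays. For these challenged arrays this islet hormone gene argues against a salivary or airway gland as the only source. Challenged wild type 3 had Ins2 at 8.87, though its exocrine genes lay only 0.66 log2 above unchallenged arrays. On the remaining challenged arrays Ins2 stood at 5.71 to 6.09. Ins2 therefore did not simply follow the exocrine level.

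Club, ciliated and smooth muscle genes, 31 in all, averaged -0.69 ± 0.057 log2 (SE over genes) in challenged mutants against challenged wild types. Single mice overlapped: challenged wild type 4 stood at -0.40 and challenged mutant 2 at -0.38, relative to the challenged wild-type mean. With array mean signal as a covariate the average difference was -0.71, although that covariate moved all probes by a median of 0.111. Lower brightness did not account for the average in this fit, but no error over mice was computed. The goblet list had a median of -0.10, against -0.90, -0.72 and -0.63 for the club, ciliated and smooth muscle lists. Goblet genes themselves rose with the challenge, to a mean of 2.29 in challenged wild types and 2.21 in challenged mutants over unchallenged wild types. Their level therefore cannot measure the amount of airway lining, and a loss of all airway lining alike stays open. With the squamous level as a covariate the average difference was again -0.71 ± 0.060 (SE over genes). Because the covariate is the mean of that list, a move of the list's own genes (median 0.730) was built in. All probes moved by a median of 0.0258. In this fit less tissue carrying these squamous genes did not account for the average, but again no error over mice was computed. Tracheal tissue without these genes was not measured, so less tracheal tissue stays open. Chance among the 8 challenged mice could not be excluded (exact two-sided permutation p = 0.0571), and an effect of the genotype stays open.

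Other splits of the arrays tested whether chance can be excluded. For challenge in wild types 1 of 35 splits, the real one, gave as many probes (3240, highest other 1). For challenge in mutants it was also 1 of 35 (4392, highest other 2473). That is the smallest share that 35 splits allow. For the count of probes chance could not be excluded for genotype without challenge (2 of 35, with 2 probes and highest other 2). Nor could it with challenge (4 of 35, with 25 probes and highest other 137). The 2 probes without challenge are those of Ifit2, and a count does not weigh how far they stood apart. The split with 137 set challenged wild types 1, 2 and 3 with mutant 2 against the rest, which points to a structure of the samples. For the interaction 100 of 100 drawn splits gave as many adjusted calls (0, highest other 21) and 34 of 100 as many at an unadjusted p under 0.05 (590, highest other 2219), the latter again pointing to a structure. For lists called at the preset correlation chance could not be excluded: 5 of 35 splits in wild types (15 lists, highest other 16), 5 of 35 in mutants (16, highest other 18), 11 of 35 without challenge (15, highest other 17), 8 of 35 with challenge (12, highest other 15) and 65 of 100 for the interaction (8, highest other 21).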

How the results depend on the processing

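The fits without doubted arrays and those with a covariate are tests chosen after the results were seen. For lists called, 2091 of 2365 comparisons over the alternatives kept direction and side of the threshold, 262 lost the call and 12 reversed. For named genes 4487 of 4845 did, 314 lost the call, 36 gained one and 8 reversed. Ifit2 kept its direction and call in every alternative run. The cause was not tested for any change below unless stated.

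For challenge in wild types (3240 probes) the count was 5410 with array weights, 2068 with a 1.5-fold minimum and 1472 with mean signal as a covariate. Since challenged arrays were dimmer, mean signal as a covariate cannot separate brightness from challenge, here or in mutants. For challenge in mutants (4392) it was 6670 with median scaling, 2531 fitting only the groups compared (fewer samples), 1665 without unchallenged mutants 1 and 3 and 563 with mean signal as a covariate. For genotype with challenge (25) it was 75 with median scaling, 12 with cyclic loess, 15 with no filter, 44 with the strict filter, 8 with array weights, 2 fitting only the groups compared, 7 without unchallenged mutants 1 and 3, and 9, 112, 53 and 52 with mean signal, skeletal muscle, squamous and pancreas levels as covariates. The interaction gave 1 with cyclic loess.

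Leaving out each array gave 2106 to 4362 probes for challenge in wild types (lowest without unchallenged wild type 2, highest without challenged mutant 4) and 2310 to 4632 in mutants (lowest without unchallenged mutant 2). It gave 2 to 36 for genotype without challenge and 0 to 8 for the interaction, both highest without unchallenged mutant 2. For genotype with challenge it gave 7 to 192, highest without challenged wild type 4, and 130 without challenged mutant 2.

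With an estimated correlation camera called 0 lists in all 5 contrasts. Fry called 19 lists for challenge in wild types, 25 for challenge in mutants, 0 for genotype without challenge, 4 with challenge and 0 for the interaction. Interaction lists numbered 5 with median scaling, 5 without challenged wild type 4 and challenged mutants 1 and 4, and 15 without unchallenged mutants 1 and 3, a fit in which 6 lists passed for genotype without challenge. That fit leaves out arrays because they were high and keeps 1 unchallenged mutant, assumed to vary like the other groups, so its signs are no independent check of direction. They were -1 for the interferon pathway, TNF and lipopolysaccharide, type 2, goblet, alternative macrophage, T cell, dendritic and MHC class I lists and 1 for the endothelial list without challenge, and 1 for the goblet and macrophage lists in the interaction, and of these reversed lists the T cell list alone passed. Mmp12 (-0.13), Clca1 (-0.35), Ccl8 (-0.13) and Ctss (-0.19) reversed there too. Cd8b1 (-0.032) and Rag1 (-0.057) reversed without challenged wild type 4 and challenged mutants 1 and 4, and Rag1 ranged from -0.23, without challenged mutant 1, to 1.60 over single arrays left out. With mean signal as a covariate Cd79a (-0.14) and the sign of the dendritic list (-1) reversed for challenge in mutants.

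The replicate block gave 16 probes for genotype with challenge. Same-numbered arrays correlated at -0.11 to 0.50 after group means were removed, above 0.1 in 9 of 21 pairs, and arrays with different numbers at -0.48 to 0.36, above 0.1 in 16 of 63. The labels give each array its own mouse, so the numbers were not taken as pairs. That 8 of 15 arrays correlated best with their own number is a hint from the data, not from the design. Exocrine pancreas genes also followed the number in both genotypes. They lay 4.02 to 8.18 log2 above unchallenged arrays on challenged arrays 1 and 2, and 0.32 to 0.66 on challenged arrays 3 and 4. Some same-numbered pairs lay below 0.1, which does not exclude a batch by replicate number, so that stays open. A slide block was not run, since no slide is given in the sources used here. Dim probes limit the signal: an array detected 39.8% to 53.6% of probes, and folds against undetected groups are bounds.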

Other observations

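The combined test of genotype over both states and the test of neighbours of Ifit2 were chosen after the results were seen.

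Single genes also changed with challenge in lists that camera called in neither genotype. Components of the interferon pathway rose in 5 of 18 cases and fell in 2 in wild types (5 and 2 adjusted over the list alone; camera adjusted p = 0.381), and rose in 4 and fell in 2 in mutants (5 and 3 adjusted over the list alone; camera adjusted p = 0.341). Of 7 complement genes 2 rose and 2 fell in wild types (2 and 2 adjusted over the list alone; camera adjusted p = 0.653), and 4 rose and 1 fell in mutants (4 and 1 adjusted over the list alone; camera adjusted p = 0.215, fry adjusted p = 0.0256). In wild types Cfb, a component of the alternative complement pathway, was 2.54-fold higher (log2 1.34 ± 0.26, SE; limma adjusted p = 0.00292). In mutants Cfb was 2.68-fold higher, a call that ended with median scaling. Natural killer and cytotoxic genes rose in 2 of 6 cases in wild types and 3 of 6 in mutants (2 and 3 adjusted over the list alone), with the perforin gene Prf1 1.80-fold higher in mutants, and the list did not pass by camera (adjusted p = 0.0725 and 0.0567), while fry called it (0.0139 and 0.00779). Fibroblast and matrix genes rose in 3 of 16 cases and fell in 4 in wild types (5 and 5 adjusted over the list alone; camera adjusted p = 0.653), and rose in 3 and fell in 5 in mutants (4 and 7 adjusted over the list alone; camera adjusted p = 0.341). Timp1, an inhibitor of matrix metalloproteinases, was 7.46-fold higher in wild types and 8.65-fold higher in mutants, and the growth factor receptor gene Pdgfra 2.08-fold and 2.27-fold lower. Alveolar type 1 genes fell in 2 of 8 cases in wild types and 5 of 8 in mutants (4 and 5 adjusted over the list alone), and 1 gene rose in each genotype (1 and 1 adjusted over the list alone), with Emp2 at -0.61 and -0.77 log2, and that list did not pass by camera either (adjusted p = 0.181 and 0.0738), while fry called it in mutants (0.0220). Of 7 erythroid and blood genes 2 rose in each genotype (2 and 2 adjusted over the list alone; camera adjusted p = 0.0725 and 0.0612), and of 9 smooth muscle genes 1 rose in wild types and 3 fell in mutants (1 and 3 adjusted over the list alone; camera adjusted p = 0.0984 and 0.173), both lists called by fry in each genotype (adjusted p from 0.0224 to 0.0422). With mean signal as a covariate Emp2 no longer passed in either genotype, nor did Cfb, Prf1 and Pdgfra in mutants.

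Across genotype in both states together 4 probes passed, both Ifit2 probes and 1 each of Ifit3 and Oas1g, both of them interferon-stimulated genes. Ifit3 is also the tested gene next to Ifit2 on chromosome 19. For Ifit3 an interferon response and a local effect near Ifit2 cannot be told apart. Ifit3 was higher in mutants by 0.59 ± 0.09 log2 (SE; limma adjusted p = 0.0431), with 0.54 without and 0.64 with challenge. The second Oas1g probe was higher by 0.76 ± 0.11 (adjusted p = 0.0262), with 0.42 and 1.10. Leaving out each array kept Ifit3 past the threshold in 6 of 15 fits (adjusted p 0.0261 to 0.128) and Oas1g in 9 of 15 (0.0114 to 0.108), with positive differences throughout. The count of 4 was 77 without unchallenged mutant 2, 22 without challenged wild type 4, 16 without challenged mutant 2 and 2 to 6 without any other array. With median scaling it was 8 and Ifit3 no longer passed (adjusted p = 0.203), and with the authors' series matrix values it was 11. Without background correction Oas1g did not pass (adjusted p = 0.0576).

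Small genotype differences near Ifit2 on chromosome 19 were also examined. The list of neighbours fixed beforehand was not called for genotype without challenge (0 of 21 genes past the threshold, 1 higher adjusted over the list alone; camera adjusted p = 0.0531, and adjusted p = 0.184 with an estimated correlation). With challenge 1 gene, Acta2, was lower past the threshold (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.324, and adjusted p = 0.493 with an estimated correlation). A hypothesis is that a flanking stretch of the chromosome was carried along with the mutation. Of the 200 tested genes nearest to Ifit2 in the order of assembly GRCm38.p6, 40 had an unadjusted p under 0.05 for genotype over both states, 24 of them lower in mutants, against a median of 22 over windows of 200 neighbouring genes. As many were found in 0.789% of 6210 windows, and the highest window on another chromosome held 36. This is consistent with such a stretch, but overlapping windows are not independent and the breeding of the mice is not given in the sources used here.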
